A study of Mus musculus with 6 samples.

How the data were processed

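RNA from mouse melan-a lines was measured on the Affymetrix Clariom S array, 2 arrays each for mKitK641E(T), mKitK641E(PT) and mVec. The titles number the arrays of a group as replicates and do not say whether these are separate cultures. Per the labels, the cells were grown in RPMI with 10% serum without treatment, total RNA was taken with RNeasy columns and labelled with biotin, and a core facility ran the arrays. The deposited values are log2 expression values, 1 per probe set and array, normalized across arrays by the authors. The software, background correction, normalization and summarizing are not given in the sources used here. The log2 unit was read from the values: gene probe sets run from 2.421 to 18.16, and their array medians lie between 5.64 and 5.89. Log2 values above 16 exceed the range of a scanner with 16 bits, which points to rescaling before deposition, a step not described in the sources used here. Differences are relative to the deposited scale. No genome build is given in the sources used here, so no positions are printed.

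The table has 28846 rows. The 22206 gene probe sets were tested, and 6640 others were left out as controls, of which 5222 are negative controls. Of the gene probe sets, 19572 carry 1 gene symbol and 2634 none, and the symbols name 19505 genes. In 142 of the gene probe sets the values equal those of another probe set on all 6 arrays, and these are counted as they stand. No filter on low values was used for the tests. For each array a background limit was taken as the 95th percentile of its negative-control probe sets (8.74 to 9.16), a choice made after seeing the data. A group counts as at background when neither of its arrays is above its limit. When 1 group is at background and the other above it, the fold is a lower bound against the limit ("at least"), and when both are at background no fold is given. Between 6433 and 7240 gene probe sets per array lay above the limit, and depth in the sense of counts does not apply to arrays.

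The deposited values were analysed as they are with R 4.3.3 and limma 3.58.1, with statmod 1.5.0. All 6 arrays entered 1 linear model with a mean for each of the 3 groups, with 3 residual degrees of freedom and a prior of 6.36 from empirical Bayes moderation without trend. The contrasts were T minus mVec, PT minus mVec and T minus PT. P-values are two-sided and were adjusted by the Benjamini-Hochberg method over all probe sets within each comparison, and a probe set was called at an adjusted p under 0.05. Replicate numbers were not used as pairs, since the deviations of equal numbers from their group means did not move together across genes (r = 0.082, 0.043 and 0.040 between the 3 pairs of groups, each from 2 numbers). No chance splits of the samples were drawn because each group has 2 arrays. The tested comparisons share groups and are not independent.

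Before the data were examined, the groups, the contrasts, the tests, the alternatives, the rule for named genes and 35 gene lists were fixed. The lists cover pigmentation, melanocyte lineage, ERK, JAK-STAT, FOXO, p53, NF-kappaB, WNT, TGF-beta, YAP and NRF2 targets, interferon response, class I antigen presentation, DNA replication, mitosis, inhibitors of cyclin-dependent kinases, the BCL2 family, mesenchymal and matrix genes, epithelial adhesion, the invasive state, glycolysis and hypoxia, oxidative phosphorylation, cholesterol synthesis, amino acid and integrated stress response, endoplasmic reticulum chaperones, lysosome and autophagy, heat shock, receptor tyrosine kinases, markers of neural crest and Schwann cells, fibroblasts, keratinocytes, leukocytes, endothelium and mast cells, and RNA quality. Of the 640 listed genes, 594 were measured, and the others are not analysed here. Each list was tested with limma's camera, using the probe set with the highest mean for each gene and a preset correlation of 0.01, and adjusted over the 35 lists within a comparison. Camera compares a list with all other genes. The test was repeated with a correlation estimated for each list. In limma this variant also uses the 3 residual degrees of freedom, where the preset form takes them from the number of genes. Its larger p-values therefore reflect both changes. Another repeat used fry. It asks whether the genes of a list move on balance in 1 direction and does not compare them with other genes.

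The named genes are Kit, Mitf, Sox10, Tyr, Dct, Mlana, Dusp6, Cdkn1a, Cdkn2a and Mki67, for each comparison the 10 largest rises and 10 largest falls by deposited log2 difference, values at background included, among called genes whose arrays do not overlap (predicted, olfactory and small RNA genes left out), and up to 4 members of each list with the largest change, called or, in a list that passed, also not called. Tyrp1, Pmel and Slc45a2, named as genes at background, Ifih1, Bst2 and Cxcl10, named as interferon genes above it, and against mVec Jun, Ier2 and Tbp, Egr1 in T and Hprt in PT, named as called RNA quality genes, fall outside this rule and were chosen after their values were seen. So were Col1a2 and Pax3, given for their means. For changes shared by the comparisons with mVec, the overlap was set against that of independent lists and against 50 simulated data sets without any change that use the same 2 controls. The overlap was also counted with a different mVec array for each Kit line, in both assignments.

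Alternatives tried were replicate number as a block, a trended and robust prior, only the 4 arrays compared, quantile normalization, median centring, only probe sets above the median mean (5.80), an unadjusted p with a 2-fold minimum, treat with a log2 difference of 0.5, estimated array weights, leaving out each array in turn and the list test variants. After leaving out an array, the lone array of that group is assumed to vary like the other groups. A filter for probe sets above background in at least 1 of the groups compared and the separate mVec arrays were chosen after seeing the data.

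The code was tested on simulated data with the spread of these arrays and 200 of 22206 probe sets changed, over 20 draws for each comparison. A log2 change of 1 was recovered in 44.3%, 47.0% and 46.0% of cases for T minus mVec, PT minus mVec and T minus PT, a change of 2 in 99.9%, 99.8% and 99.9%, and a change of 0.5 in 2.16%, 1.19% and 1.79%. Of the simulated calls, 7.48%, 9.20% and 7.15% were false. A shifted list was found in 20 of 20 draws in each comparison. Lists left unshifted were called 0, 2 and 1 times over these draws. Genes were simulated as independent, so the preset correlation of the list test was not tested by this. All comparisons were simulated from the same means and spread, so their percentages are repeats of 1 setting. In the real data, 32.4% of probe sets were called in T against mVec and 35.9% in PT, far more than were changed here. The recovered and false shares therefore need not hold for the real comparisons.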

Results

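Transcript levels were measured on 6 Affymetrix Clariom S mouse arrays from lines made from melan-a, an immortalized melanocyte line of the C57BL/6J strain. The labels give 3 groups of 2 arrays each. The mVec line carries a control vector and is labelled as melanocytes. The lines mKitK641E(T) and mKitK641E(PT), called T and PT here, carry Kit with the K641E substitution and are labelled as melanoma cells transformed by it. Kit is the receptor tyrosine kinase for stem cell factor in melanocytes, and K641E is a known activating substitution. The titles call the T arrays C3# and the PT arrays hi exp. The meaning of T, PT and these titles is not given in the sources used here. Each array gave log2 values for 22206 gene probe sets, with array medians from 5.64 to 5.89. Between 29.0% and 32.6% of these probe sets lay above the background limit of their array, which was the 95th percentile of 5222 negative-control probe sets and fell between 8.74 and 9.16. Across genes, the 2 arrays of a group correlated at r = 0.993 in T, 0.994 in PT and 0.995 in mVec, and genes are not independent replicates. With 2 arrays per group, the number of arrays limits the precision of every value. Each group is 1 line, so errors and p-values of single genes measure the spread between arrays of a line and not between lines. The camera p-values with the preset correlation instead set a list against all other genes, with degrees of freedom taken from the number of genes. They rest on the spread between genes, taken as nearly independent, and do not measure the spread between lines either. Each error below is the standard error of the limma fit.

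Kit was read first, as the gene whose mutant form was introduced. Its probe set was not above background on any of the 6 arrays. The log2 values were 4.53 and 5.18 in T, 4.53 and 3.84 in PT, and 4.68 and 4.97 in mVec. None of the 3 differences passed the limma test: T minus mVec was 0.03 ± 0.30 (adjusted p = 0.956), PT minus mVec was -0.63 ± 0.30 (adjusted p = 0.141) and T minus PT was 0.67 ± 0.30 (adjusted p = 0.225). The T minus mVec value changed sign when 1 array was left out, to -0.29 without T replicate 2 and to -0.11 without mVec replicate 1, and its highest value was 0.36, without T replicate 1. The lowest mean, 4.19, was that of PT, the line titled hi exp. The Kit values therefore give no check of the labels, and the arrays were grouped as labelled.

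Most pigment cell genes were at background too. The pigment enzymes Tyr, Tyrp1 and Dct, the melanosome proteins Pmel and Mlana, the transporter Slc45a2 and the transcription factor Sox10 were not above background on any array. Of the 21 measured pigmentation genes, 18 were at background in both groups of each comparison. At background does not mean equal: Slc24a5 of this list, under the limit on every array, had means of 7.44 in mVec, 4.01 in T and 4.18 in PT. In the list, 0 genes were called higher than in mVec in either line. Gpnmb, a glycoprotein of melanosomes and lysosomes, was bright in every group. Its mean was 15.27 in mVec, and it fell by 1.45 ± 0.20 in T (adjusted p = 0.000285) and by 2.42 ± 0.20 in PT (adjusted p = 6.7e-06). Mitf, the master transcription factor of melanocytes, was above background on both T arrays (mean 9.06) and at background in PT (8.86) and mVec (8.03). It was at least 1.04-fold higher in T than in mVec (log2 difference 1.03 ± 0.20, adjusted p = 0.00314). Mitf was called higher in PT than in mVec as well (limma adjusted p = 0.00901), with both groups at background. That call in PT was lost in 2 alternatives. In the pigmentation list, 6 genes were lower in T than in mVec (6 adjusted over the list alone), 5 of them at background in both groups, and the list did not pass its camera test (adjusted p = 0.0821). In PT, 8 of its genes were called lower (8 adjusted over the list alone), 6 of them at background in both groups, where no fold is given, and the list passed (adjusted p = 0.0314), but not with an estimated correlation (adjusted p = 0.244) or among probe sets above the median mean (0.0844), with a range over its 13 alternatives from 0.00146 to 0.244. Of the 14 measured melanocyte lineage genes, 2 were higher and 5 lower in T (3 and 5 adjusted over the list alone), with no call for the list (adjusted p = 0.191). In PT, 3 were higher and 5 lower (3 and 5 adjusted over the list alone), again with no call for the list (camera adjusted p = 0.437). The lineage gene Tbx2 was at least 4.15-fold lower in T and at least 3.66-fold lower in PT than in mVec.

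**Figure D1:**
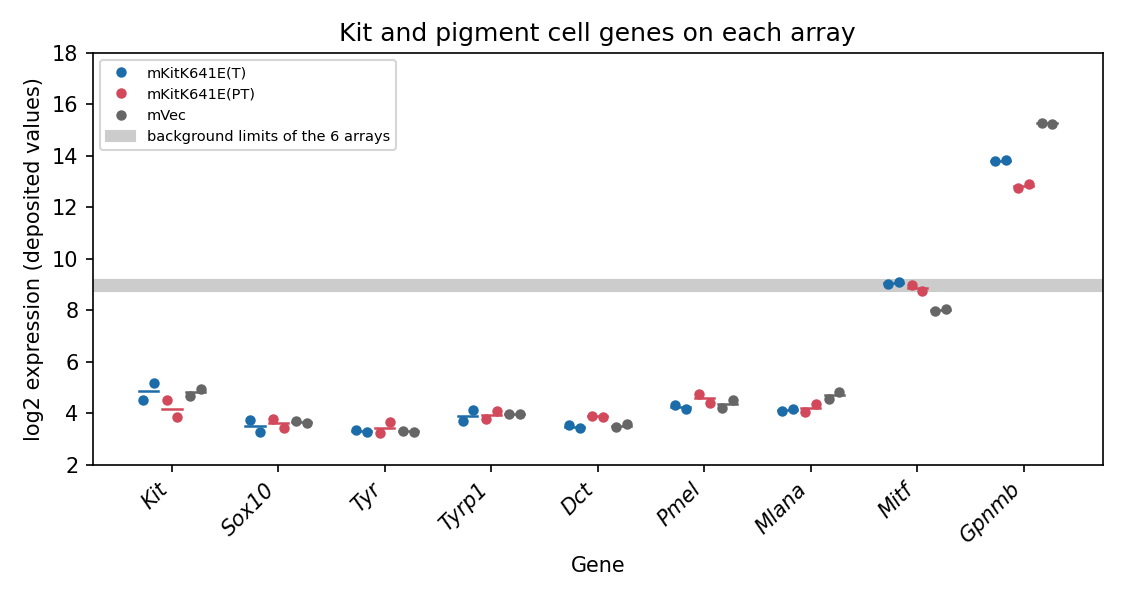
Deposited log2 expression (vertical axis) of Kit and 8 pigment cell genes (horizontal axis) on each array. Points are single arrays, short lines are the means of the 2 arrays of a group, and the grey band spans the background limits of the 6 arrays, 8.74 to 9.16. Kit lies between 3.84 and 5.18 on all 6 arrays, while Gpnmb lies above the band in every group.

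The comparison of T with mVec asks which transcripts differ between cells carrying mutant Kit and cells carrying the vector. Interferon-stimulated genes, the antiviral genes switched on by interferon, were mostly above background in mVec, with 20 of 28 measured genes on both arrays, and mostly at background in T, where 3 were above it, Ifih1, Bst2 and Cxcl10. Ifit3, an interferon-induced antiviral protein, was at least 95.4-fold lower in T (log2 difference -9.24 ± 0.22), Oasl2 at least 70.2-fold lower and Xaf1 at least 61.0-fold lower. Of the 28 measured genes of the interferon list, 25 fell and 0 rose (26 and 0 adjusted over the list alone), with a median of -4.63, or -2.74 with bounds, where genes at background in 1 of the groups are set to their bound. The camera test gave an adjusted p of 7.4e-22, and 0.0478 with an estimated correlation. The class I antigen presentation list moved the same way, with 10 of 15 genes lower and 1 higher (10 and 1 adjusted over the list alone; adjusted p = 0.000441, and 0.212 with an estimated correlation). Its members included H2-T23, a nonclassical class I molecule, at least 11.7-fold lower, and the proteasome activator Psme1 (-2.74 ± 0.21).

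Extracellular matrix genes were also lower in T than in mVec. Postn, a matrix protein of connective tissue, was at least 88.4-fold lower, the collagen gene Col1a1 at least 78.8-fold lower and Tgfbi, a matrix protein induced by TGF-beta, at least 69.1-fold lower. In the mesenchymal and matrix list, 19 of 27 genes fell and 1 rose (19 and 1 adjusted over the list alone; median -1.69, or -1.40 with bounds, adjusted p = 1.13e-10, and 0.0559 with an estimated correlation). Large falls outside the lists included Aspn, a small matrix proteoglycan (at least 113-fold), Plxdc2 (at least 129-fold), the lipocalin Apod (at least 89.7-fold), the laminin chain Lama4 (at least 36.9-fold) and the matrix protease Mmp3 (at least 56.5-fold). Fibroblast markers, kept as a list of another cell type, moved with these genes: 6 of 12 fell and 2 rose (6 and 2 adjusted over the list alone; adjusted p = 0.0167, and 0.212 with an estimated correlation). This list shares Col1a1, Col1a2 and Col3a1 with the matrix list, and its other members included the proteoglycan Dcn, at least 35.6-fold lower. Col1a2 went the other way from Col1a1 and Col3a1, with means of 9.23 in T and 9.22 in PT against 5.07 in mVec, where it was at background. TGF-beta targets had 10 of 15 genes lower and 2 higher (10 and 3 adjusted over the list alone; adjusted p = 0.000604, and 0.212 with an estimated correlation), among them Id3, at least 8.55-fold lower, and Bhlhe40 (-3.78 ± 0.24).

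Cell division genes were higher in T than in mVec. All 24 measured mitosis genes rose (24 adjusted over the list alone), with a median of 2.74, or 1.91 with bounds, and the list passed with the preset correlation (adjusted p = 2.3e-15) and with an estimated correlation (adjusted p = 0.0478). Cdc20, the activator of the anaphase-promoting complex, was at least 2.67-fold higher, the mitotic kinase Cdk1 at least 5.79-fold higher and the proliferation marker Mki67 4.47-fold higher (log2 difference 2.16 ± 0.25). Of 24 DNA replication genes, 22 rose and 0 fell (22 and 0 adjusted over the list alone; median 2.83, or 1.84 with bounds, adjusted p = 1.03e-12, and 0.212 with an estimated correlation), with the helicase subunit Mcm5 at least 5.57-fold and the ribonucleotide reductase subunit Rrm2 at least 7.33-fold higher. Among 7 inhibitors of cyclin-dependent kinases, 4 fell and 1 rose (4 and 1 adjusted over the list alone; median -1.63, adjusted p = 0.0182, and 0.213 with an estimated correlation). Cdkn2c, also known as p18, fell by 5.13 ± 0.27 and was above background on 1 of the T arrays. The values of Cdkn1a and Cdkn2a did not pass the test (-0.13 ± 0.25 and -0.34 ± 0.20).

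All 20 measured genes of amino acid synthesis and the integrated stress response rose in T (20 adjusted over the list alone; median 2.66, or 2.08 with bounds, adjusted p = 1.03e-12, and 0.212 with an estimated correlation). They included the serine synthesis enzyme Psph (3.48 ± 0.22), the mitochondrial folate enzyme Aldh1l2 (3.80 ± 0.21) and the stress transcription factor Atf3, at least 9.77-fold higher, which also belongs to the RNA quality list. In the cholesterol synthesis list, 10 of 16 genes rose and 1 fell (11 and 1 adjusted over the list alone; median 1.01, adjusted p = 0.000241, and 0.212 with an estimated correlation), with the sterol enzyme Msmo1 at least 17.1-fold and the lanosterol synthase Lss 11.0-fold higher (3.46 ± 0.20). Large rises outside the lists included Pde3b, a cyclic nucleotide phosphodiesterase (at least 33.6-fold), Bcat1, an enzyme of branched-chain amino acid breakdown (at least 47.4-fold), Crabp2, a retinoic acid binding protein (at least 25.2-fold), Gprc5a (at least 16.5-fold), Foxr2, a forkhead transcription factor (at least 29.0-fold), and the choline kinase Chka (at least 31.4-fold).

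Genes that respond to ERK signalling, a pathway downstream of Kit, moved in both directions in T. Of 21 measured genes, 11 fell and 5 rose (11 and 5 adjusted over the list alone; median -0.84, adjusted p = 0.0492, and 0.473 with an estimated correlation). Fos was at least 40.6-fold lower and the ERK phosphatase Dusp6 fell by 1.44 ± 0.20, while the AP-1 subunit Fosl1 rose by 4.15 ± 0.34 and the receptor Epha2 by 3.77 ± 0.22. Fos and Egr1 (-2.19 ± 0.22) also belong to the RNA quality list, in which further immediate early genes fell with them. Fosb was at least 4.11-fold lower, and Jun (-1.20 ± 0.20) and Ier2 (-1.28 ± 0.35, adjusted p = 0.0175) were called lower. The stress gene Atf3 of the same list was called higher. The Ier2 call was lost without T replicate 1 (adjusted p = 0.121) and without mVec replicate 2 (0.122), with a range over its alternatives from 0.00175 to 0.122. The ERK call was lost without T replicate 1 (adjusted p = 0.0663), without mVec replicate 1 (0.0563), without mVec replicate 2 (0.0854), with camera on ranks (0.0515), among probe sets above the median mean (0.0889) and among those above background (0.0706), and over its 14 alternatives the adjusted p ran from 0.00891 to 0.473. FOXO targets had 9 of 18 genes lower and 2 higher (10 and 3 adjusted over the list alone; median -0.84, adjusted p = 0.00508, and 0.242 with an estimated correlation), including the sestrin Sesn3 (-4.17 ± 0.20). Among receptor tyrosine kinases and their ligands, 16 of 33 fell and 2 rose (16 and 2 adjusted over the list alone; adjusted p = 0.000396, and 0.176 with an estimated correlation), with the growth factor Igf1 at least 31.9-fold and the receptor Mertk at least 7.10-fold lower.

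In total, limma called 7201 of the 22206 probe sets between T and mVec, 3763 higher and 3438 lower in T, and 2772 and 2577 of these differed by at least 2-fold. In 2006 of the called probe sets both groups were at background, so that no fold is given for them. 766 probe sets were above background in mVec and at background in T, and 682 the reverse. Of the calls, 52.3% were higher in T, and 62.3% when each array was centred on its median, which raised every log2 difference by 0.18. Of the 35 gene lists, 4 passed as higher and 9 as lower, and 2 of these 13, mitosis and interferon response, also passed with an estimated correlation, which gave the highest adjusted p among the alternatives for all 13. With camera on ranks, the calls of fibroblast markers (adjusted p = 0.122, range over the alternatives 0.000237 to 0.212) and of inhibitors of cyclin-dependent kinases (0.0515, range 0.000853 to 0.213) were lost, and among genes above background that of class I antigen presentation (0.0542, range 0.000264 to 0.212). The called members of a list that were at background in both groups were 4 of the 25 lower interferon genes, 4 of the 16 lower receptor tyrosine kinases and ligands, 2 of the 10 lower antigen presentation genes and 2 of the 22 higher DNA replication genes, among others.

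The comparison of PT with mVec asks the same question of the other Kit line. Most interferon genes were at background in PT as well, with 3 of 28 above it, again Ifih1, Bst2 and Cxcl10. Ifit3 was at least 84.2-fold, Oasl2 at least 62.0-fold and Xaf1 at least 53.9-fold lower than in mVec. In the list, 25 of 28 genes fell and 1 rose (25 and 1 adjusted over the list alone; median -4.57, or -2.73 with bounds, adjusted p = 1.55e-19, and 0.0404 with an estimated correlation). Class I antigen presentation had 11 of 15 genes lower and 1 higher (11 and 1 adjusted over the list alone; adjusted p = 2.17e-05, and 0.170 with an estimated correlation), including Tapbp, which loads peptides onto class I molecules (-3.40 ± 0.29). In the mesenchymal and matrix list, 19 of 27 genes fell and 1 rose (21 and 1 adjusted over the list alone; median -1.94, or -1.34 with bounds, adjusted p = 1.06e-10, and 0.0549 with an estimated correlation), with Col3a1 at least 111-fold and Postn at least 78.0-fold lower. The fibroblast list, which moved with it, had 6 of 12 genes lower and 2 higher (6 and 2 adjusted over the list alone; adjusted p = 0.0193, and 0.244 with an estimated correlation). TGF-beta targets had 10 of 15 genes lower and 2 higher (10 and 2 adjusted over the list alone; median -2.23, adjusted p = 4.76e-05, and 0.170 with an estimated correlation), with Id2 at -4.67 ± 0.21. Other large falls were Efemp1, a fibulin of the matrix (at least 175-fold), the circadian transcription factor Dbp (at least 108-fold), the peptidase Mme (at least 57.2-fold) and Aspn (at least 99.5-fold).

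Cell division genes rose in PT. All 24 mitosis genes were higher (24 adjusted over the list alone; median 3.96, or 3.11 with bounds, adjusted p = 3.3e-17, and 0.0404 with an estimated correlation), with Cdc20 at least 8.16-fold, the mitotic kinase Aurka at least 9.13-fold, the cyclin Ccna2 at least 19.6-fold and Mki67 8.13-fold higher (3.02 ± 0.25). Of 24 DNA replication genes, 22 rose and 0 fell (23 and 0 adjusted over the list alone; median 3.06, or 2.18 with bounds, adjusted p = 9.53e-13, and 0.175 with an estimated correlation), with the helicase subunit Mcm3 at least 25.9-fold higher. In the amino acid and stress response list, 17 of 20 genes rose and 0 fell (18 and 1 adjusted over the list alone; median 2.14, or 1.89 with bounds, adjusted p = 6.37e-09, and 0.272 with an estimated correlation), with Psph at 4.09 ± 0.22 and Atf3 at least 9.32-fold higher. The cholesterol synthesis list had 7 genes higher and 4 lower of 16 (8 and 4 adjusted over the list alone) and did not pass (adjusted p = 0.437). Large rises outside the lists again included Pde3b (at least 33.5-fold), Phlda2 (at least 13.6-fold), Gprc5a (at least 30.7-fold), Bcat1 (at least 52.9-fold) and Foxr2 (at least 34.5-fold), together with Rrp12, a ribosome assembly factor (at least 8.14-fold).

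ERK targets had 12 genes lower and 4 higher of 21 in PT (12 and 4 adjusted over the list alone; median -1.17, or -0.69 with bounds, adjusted p = 0.0158, and 0.444 with an estimated correlation). Fos was at least 35.9-fold and the transcription factor Etv1 at least 20.6-fold lower, Dusp6 fell by 1.61 ± 0.20, and Epha2 rose by 5.11 ± 0.22. The same immediate early genes of the RNA quality list fell in PT too, with Egr1, shared with the ERK list, at -4.06 ± 0.22, Fosb at least 3.63-fold lower, Ier2 at -2.21 ± 0.35 and Jun at -1.30 ± 0.20. Atf3 of that list was again called higher. FOXO targets had 9 genes lower and 2 higher of 18 (10 and 2 adjusted over the list alone; median -1.30, adjusted p = 0.00226, and 0.244 with an estimated correlation), with Sesn3 at least 25.4-fold lower. Receptor tyrosine kinases and ligands had 16 genes lower and 3 higher of 33 (16 and 3 adjusted over the list alone; adjusted p = 0.00226, and 0.170 with an estimated correlation). Among the 7 inhibitors of cyclin-dependent kinases, 4 fell and 1 rose (4 and 2 adjusted over the list alone; median -1.79, or -1.52 with bounds, adjusted p = 0.0493, and 0.272 with an estimated correlation), with Cdkn2c at least 28.2-fold lower. The riser was Cdkn1a, by 1.14 ± 0.25 (adjusted p = 0.00433), a call lost without mVec replicate 2 (0.0505, with a range over its alternatives from 0.000312 to 0.0505), and Cdkn2a did not pass (-0.22 ± 0.20). The call of the list was lost without T replicate 1 or T replicate 2 (adjusted p = 0.0544 each), whose arrays enter through the shared error estimate, and without mVec replicate 2 (0.0560). It was also lost with replicate number as a block (0.0669), with camera on ranks (0.209), among probe sets above the median mean (0.0815) and among those above background (0.161), and over its 14 alternatives the adjusted p ran from 0.00051 to 0.272.

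In total, 7975 probe sets were called between PT and mVec, 3981 higher and 3994 lower in PT, of which 2895 and 3150 differed by at least 2-fold. Both groups were at background in 2325 of them, 1042 went from above background in mVec to background in PT, and 735 the reverse. Of the calls, 49.9% were higher in PT, and 60.3% under median centring, which raised every log2 difference by 0.19. Of the 35 lists, 3 passed as higher and 10 as lower. The mitosis and interferon lists again passed with an estimated correlation, which gave the highest adjusted p among the alternatives for all 13. The call of ERK targets was lost among probe sets above the median mean (adjusted p = 0.0844) and among those above background (0.0909), with a range from 0.00291 to 0.444, and that of fibroblast markers with camera on ranks (0.117, range 0.000123 to 0.244). Called members at background in both groups were 4 of the 25 lower interferon genes, 4 of the 16 lower receptor tyrosine kinases and ligands, 3 of the 11 lower antigen presentation genes and 2 of the 22 higher DNA replication genes, among others.

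**Figure D2:**
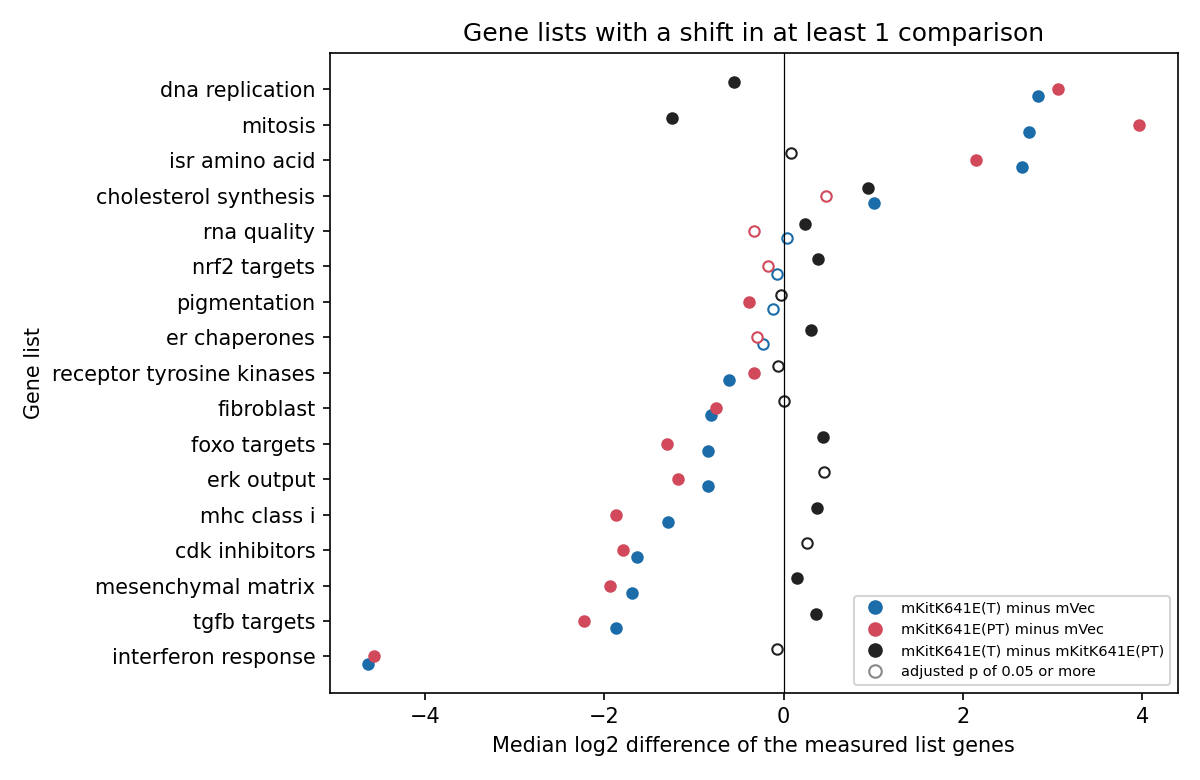
Median log2 difference of the measured genes, from the deposited values without bounds (horizontal axis) of each gene list that passed the camera test in at least 1 of the 3 comparisons (vertical axis). Filled points passed at an adjusted p under 0.05 and open points did not. The interferon list lies at -4.63 and -4.57 in the comparisons with mVec, and the mitosis list at 2.74 and 3.96.

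**Figure D3:**
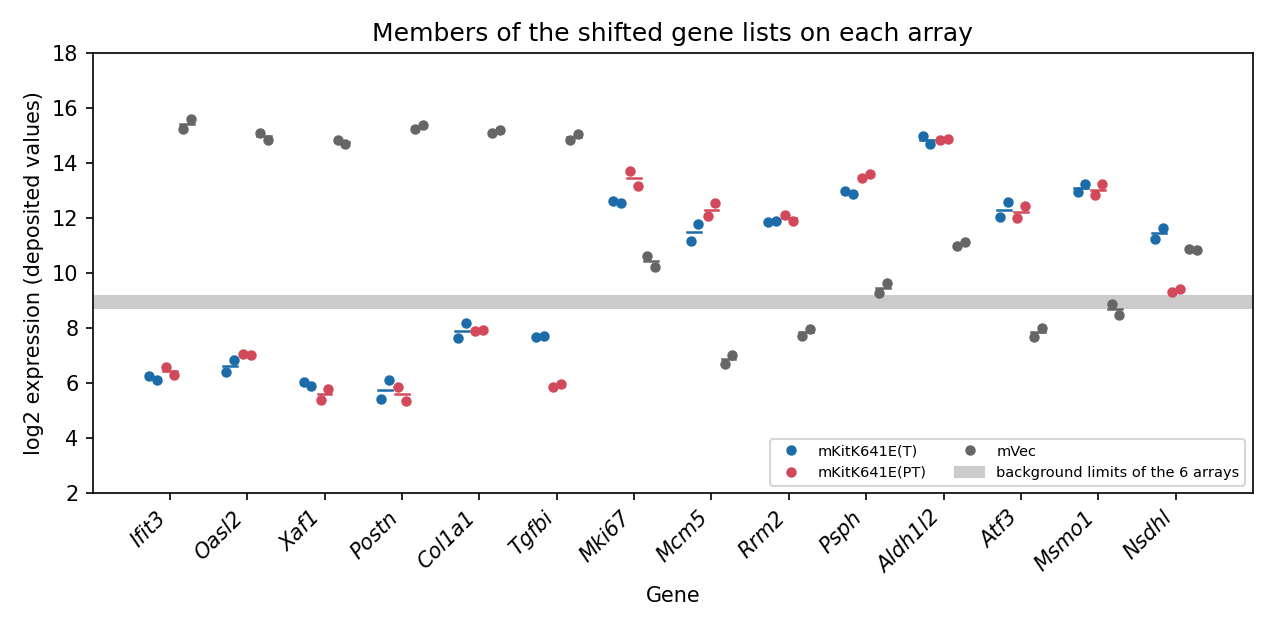
Deposited log2 expression (vertical axis) of 14 named members of the gene lists (horizontal axis) on each array. Points are single arrays, short lines are group means of 2 arrays, and the grey band spans the background limits of the 6 arrays. Ifit3, Oasl2, Xaf1, Postn, Col1a1 and Tgfbi lie above the band in mVec and below it in T and PT.

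The changes against mVec were largely shared by the Kit lines. Of the probe sets called in T, 3067 were called higher and 3017 lower in both lines, against 674.6 and 618.4 for independent lists of these sizes, and 24 were called in opposite directions, against 1293 for independent lists. Those called in both lines in the same direction made up 84.5% of the T calls and 76.3% of the PT calls. Across genes the log2 differences correlated at r = 0.93, with a covariance of 1.77. Both comparisons use the same 2 mVec arrays, which alone produces a correlation: simulated groups without any change gave r = 0.50, a covariance of 0.031 and 0.06 probe sets called alike, as means of 50 simulations. When each Kit line was compared with a different mVec array, a choice made after seeing the data, the covariance was 1.74 in both of the possible assignments and the correlation 0.90. Then 4684 and 4710 probe sets were called in the same direction, against 823.7 and 831.1 for independent lists, and 5 and 7 in opposite directions. These fits take their spread from the T and PT arrays, and both mVec arrays come from 1 line. How T and PT were derived, and whether either came from the other, is not given in the sources used here. Their arrays correlated at r = 0.982 to 0.989 across genes. The shared calls therefore cannot be taken as 2 independent tests of mutant Kit. The 24 probe sets with opposite calls included Actn1, an actin crosslinker, at -1.07 in T and 1.39 in PT, and Ccbe1, at -0.95 and 1.43, both relative to mVec. Without single arrays this count ran from 1, without mVec replicate 2, to 32, without T replicate 1.

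The direct comparison of T with PT asks how the Kit lines differ from each other. Cell division genes were lower in T than in PT. Of 24 mitosis genes, 16 were lower and 0 higher (20 and 0 adjusted over the list alone; median -1.25, adjusted p = 3.25e-15, and 0.0942 with an estimated correlation). The mitotic kinase Nek2 fell by 2.14 ± 0.20, the spindle protein Nusap1 by 2.01 ± 0.22 and the centromere histone Cenpa by 1.92 ± 0.22. The difference of Mki67 did not pass (-0.86 ± 0.25, adjusted p = 0.0679). Cdkn1a was lower in T than in PT by 1.27 ± 0.25 (adjusted p = 0.0144), a call lost without T replicate 2 (0.0831) and without PT replicate 1 (0.115), with a range over its alternatives from 0.00114 to 0.115, and Cdkn2a did not pass (-0.12 ± 0.20). DNA replication genes had 4 lower and 0 higher of 24 (9 and 0 adjusted over the list alone; median -0.56, adjusted p = 0.000617, and 0.581 with an estimated correlation), with Mcm3 at -1.54 ± 0.24. The kinetochore subunit Ndc80 (-2.42 ± 0.24), the spindle protein Tacc3 (at least 2.69-fold lower), Actn1 (-2.46 ± 0.24) and the matrix protein Npnt (at least 2.05-fold lower) were among the large falls outside the lists.

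Cholesterol synthesis genes were higher in T than in PT, with 8 of 16 higher and 0 lower (10 and 0 adjusted over the list alone; median 0.94, adjusted p = 8.63e-08, and 0.277 with an estimated correlation). The sterol enzyme Nsdhl rose by 2.08 ± 0.22, the synthase Hmgcs1 by 1.67 ± 0.21 and the sterol sensor partner Insig1 by 1.67 ± 0.20. NRF2 targets, genes of the oxidative stress response, had 7 of 18 higher and 0 lower (7 and 0 adjusted over the list alone; 2 of the 7 at background in both groups; median 0.39, adjusted p = 0.000209, and 0.277 with an estimated correlation), including the glutathione transferase Gstm1 (2.44 ± 0.20). TGF-beta targets had 5 of 15 higher and 0 lower (5 and 0 adjusted over the list alone; 3 of the 5 at background in both groups; adjusted p = 0.000617, and 0.315 with an estimated correlation), with Id2 at 1.51 ± 0.21. FOXO targets had 5 of 18 higher and 0 lower (8 and 0 adjusted over the list alone; adjusted p = 0.00184, and 0.365 with an estimated correlation), with Sesn3 at least 1.41-fold higher. The mesenchymal and matrix list had 5 of 27 higher and 1 lower (5 and 1 adjusted over the list alone; 2 of the 5 at background in both groups; adjusted p = 0.0145, and 0.321 with an estimated correlation), with smooth muscle actin, Acta2, at least 5.62-fold and Col3a1 at least 1.10-fold higher. Other large rises were the matrix proteins Efemp1 (at least 2.77-fold) and Fbln5 (3.41 ± 0.21) and the serine synthesis enzyme Phgdh (at least 1.32-fold).

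Leaving out single arrays ended the calls of class I antigen presentation, endoplasmic reticulum chaperones and RNA quality between T and PT. In the antigen presentation list 1 of 15 genes, at background in both lines, was higher and 0 lower (5 and 0 adjusted over the list alone; median 0.38, adjusted p = 0.00817, and 0.375 with an estimated correlation), and the call was lost without PT replicate 1 (adjusted p = 0.0529, with a range over all 14 alternatives from 0.00359 to 0.382). The chaperone list had 2 of 15 genes higher and 1 lower (4 and 1 adjusted over the list alone; median 0.30, adjusted p = 0.0474, and 0.581 with an estimated correlation), with the transcription factor Xbp1 at 1.89 ± 0.21. Its call was lost without T replicate 1 (adjusted p = 0.263), PT replicate 1 (0.185), mVec replicate 1 or mVec replicate 2 (0.0567 each), with a range over all alternatives from 0.0179 to 0.581. In the RNA quality list, which moved with these gene groups, 1 of 16 genes was higher and 0 lower in T (1 and 0 adjusted over the list alone; median 0.24, adjusted p = 0.0285, and 0.621 with an estimated correlation), the immediate early gene Egr1 at 1.86 ± 0.22. Its call was lost without T replicate 1 (adjusted p = 0.0683) and PT replicate 1 (0.403), with a range from 0.00308 to 0.621. The ERK list was not called (median 0.45, or 0.31 with bounds, adjusted p = 0.0773; 5 of 21 higher and 2 lower, 7 and 2 adjusted over the list alone) and passed without T replicate 2 (adjusted p = 0.0464) or PT replicate 2 (0.0207).

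Other settings ended further calls between T and PT. The mesenchymal and matrix call was lost among probe sets above the median mean (adjusted p = 0.248) and among those above background (0.531), with a range over its 14 alternatives from 0.00982 to 0.531. Among genes above background, the calls of FOXO targets (adjusted p = 0.0704, range 0.000678 to 0.365), NRF2 targets (0.120, range 8.63e-05 to 0.277) and TGF-beta targets (0.384, range 0.000466 to 0.384) were lost too. The same filters ended the calls of antigen presentation (0.0979 above the median mean and 0.382 above background), chaperones (0.326 and 0.382) and RNA quality (0.261 and 0.354). The chaperone call was also lost with camera on ranks (0.0540) and after quantile normalization (0.0537). With fry, RNA quality (0.0883) and DNA replication (0.0640, range over its alternatives 2.19e-05 to 0.581) did not pass. Lists that were not called in this comparison (adjusted p from 0.162 to 0.336) and passed without PT replicate 2 were amino acid and integrated stress response (adjusted p = 0.0311), lysosome and autophagy (0.0206), oxidative phosphorylation (0.0207) and leukocytes (0.0207).

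In total, limma called 1857 probe sets between T and PT, 1258 higher and 599 lower in T, of which 927 and 390 differed by at least 2-fold and 560 had both groups at background. The count rested on single arrays: 659 were called without T replicate 2, 549 without PT replicate 1 and 801 without PT replicate 2, against 1714 without T replicate 1. With a required log2 difference of 0.5 in limma's treat test, 294 were called higher and 76 lower. Of the 1258 probe sets higher in T than in PT, 927 were called lower in PT than in mVec. T lay between mVec and PT in 61.8% of the 1258, against 45.5% of all probe sets. Of the 599 lower in T, 466 were called higher in PT than in mVec, and T lay between in 67.8% of the 599. Of the 35 lists, 8 passed as higher and 2 as lower in T, and 0 of these 10 passed with an estimated correlation.

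Markers of other cell types were mostly at background. None of the 14 measured leukocyte genes and none of the 12 keratinocyte genes was above background on both arrays of any group. The endothelial cadherin Cdh5 was above background in mVec, as 1 of 11 endothelial genes, and at least 3.54-fold lower in T. Of 10 mast cell genes, 1 was above background in T and in PT, the transcription factor Gata2, which was above it on 1 mVec array. Of 12 fibroblast genes, 5 were above background in mVec, 2 in T and 0 in PT, and of 16 neural crest and Schwann cell genes 4 were above it in mVec, 2 in T and 2 in PT. In the latter list the transcription factor Tfap2b was at least 18.8-fold and the water channel Aqp1 at least 39.8-fold lower in T than in mVec. Of the 16 RNA quality genes, 14 were above background in T, 14 in PT and 15 in mVec. That list did not pass against mVec in T (adjusted p = 0.747) or in PT (adjusted p = 0.286), with 3 genes higher and 5 lower in each (3 and 5 adjusted over the list alone). These were the same genes in both lines, Atf3, Hprt and Tbp as higher and the immediate early genes Fos, Fosb, Egr1, Jun and Ier2 as lower.

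18 of the 35 lists passed in none of the 3 comparisons, with camera adjusted p from 0.157 to 0.976. These were melanocyte lineage, JAK-STAT targets, p53 targets, the BCL2 family, NF-kappaB cytokines, epithelial adhesion, the invasive state, YAP targets, neural crest and Schwann cells, WNT targets, glycolysis and hypoxia, oxidative phosphorylation, lysosome and autophagy, heat shock, keratinocytes, leukocytes, endothelium and mast cells. Single members of these lists were still called. The death receptor Tnfrsf10b, a p53 target, was at least 5.12-fold higher in T and at least 14.9-fold higher in PT than in mVec. The chemokine Cxcl12 was at least 24.6-fold and 21.7-fold lower in T and PT, and the growth factor Nrg1 of the invasive state list at least 6.15-fold and 14.5-fold higher. The YAP target Ankrd1 rose by 4.72 ± 0.20 in T and by 5.27 ± 0.20 in PT. Some lists had a median, mean and test that differed in sign: 5 in T against mVec, 5 in PT against mVec and 6 in T against PT, of which 0 passed their test. The 5 in T were p53 targets, epithelial adhesion, NRF2 targets, leukocytes and RNA quality, the 5 in PT were melanocyte lineage, epithelial adhesion, YAP targets, lysosome and autophagy, and endothelium, and the 6 between T and PT were pigmentation, p53 targets, interferon response, NF-kappaB cytokines, the invasive state and heat shock.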

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

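The difference between the effects in T and in PT, both against mVec, was tested as T minus PT with limma or camera, a comparison fixed before the results were seen. The gene lists below passed that test with the preset correlation, and 0 of the 10 passed with an estimated correlation. The mitosis list had a median T minus PT difference of -1.25 and the DNA replication list one of -0.56, both lists being higher than mVec in both lines. The medians of the other lists were 0.94 for cholesterol synthesis, 0.44 for FOXO targets (0.30 with genes at background in 1 group set to their bound), 0.39 for NRF2 targets, 0.38 for class I antigen presentation, 0.36 for TGF-beta targets, 0.30 for endoplasmic reticulum chaperones, 0.24 for RNA quality and 0.15 for mesenchymal and matrix genes. Leaving out 1 array ended the call of the chaperone list (adjusted p = 0.263 without T replicate 1, 0.185 without PT replicate 1 and 0.0567 without either mVec array), of the RNA quality list (0.0683 without T replicate 1 and 0.403 without PT replicate 1) and of antigen presentation (0.0529 without PT replicate 1). These lists' alternatives ranged from 0.0179 to 0.581, from 0.00308 to 0.621 and from 0.00359 to 0.382. Among genes above background, a filter chosen after the results were seen, the calls of FOXO targets (adjusted p = 0.0704), NRF2 targets (0.120), TGF-beta targets (0.384) and mesenchymal and matrix genes (0.531) were lost as well.

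Single named genes differed too. Actn1 was lower than mVec in T (-1.07) and higher in PT (1.39), and its T minus PT difference was -2.46. Ccbe1 was lower in T (-0.95) and higher in PT (1.43), and its T minus PT difference was -2.38.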

How the results depend on the processing

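The filter for probe sets above background and the separate mVec array for each Kit line were chosen after the results were seen, and the other alternatives before. No alternative changed the direction of a named gene or list that was called, and 0 called probe sets were called the other way under the settings of the gene counts. The counts of genes against mVec stayed within 1.5 times their main value, except under treat with a log2 difference of 0.5, which asks for a larger change: 2356 higher and 2195 lower in T, and 2589 higher in PT. Between T and PT, treat left 294 higher and 76 lower, the trended and robust prior gave 950 lower and the background filter 924 lower (the cause was not tested for the latter pair). Leaving out single arrays, which removes samples from the fit, gave 370 to 1119 higher and 176 to 595 lower between T and PT, 2908 to 3751 higher and 2689 to 3350 lower in T against mVec, and 3152 to 4103 higher and 3316 to 4098 lower in PT against mVec. With replicate number as a block, although the numbers do not pair across genes, the calls were 7330, 8054 and 1819 in T against mVec, PT against mVec and T against PT. With a correlation estimated for each list, 1 list was higher and 1 lower in T, 1 and 1 in PT, and 0 and 0 between T and PT. Fry, which does not compare a list with other genes, gave 10 higher and 19 lower in T and 7 higher and 22 lower in PT. Between T and PT, 4 lists were higher among probe sets above the median mean and 1 among genes above background, each with fewer genes tested, and without single arrays 5 to 12 were higher and 2 to 3 lower. Without single arrays, 4 lists were higher and 8 to 9 lower in T, and 3 higher and 9 to 10 lower in PT. Probe sets called in opposite directions in T and PT against mVec numbered 45 among those above the median mean, 2 with an unadjusted p and 2-fold, 5 and 7 with separate mVec arrays, and 1 to 32 without single arrays, and those in the same direction 4878 to 5635, with a correlation from 0.90 to 0.94.

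Values without a call, near 0, changed sign under some settings, and the cause was not tested. Under median centring, Dct (0.14) and Cdkn1a (0.0547) in T and Sox10 (0.12) in PT, all against mVec, became positive. Without single arrays, against mVec in T, Kit ran from -0.29 to 0.36, Sox10 from -0.42 to 0.0457, Tyr from -0.0303 to 0.0304, Dct from -0.0966 to 0.0119 and Cdkn1a from -0.39 to 0.13. In PT, Sox10 ran from -0.23 to 0.0940 and Tyr from -0.0785 to 0.36. Between T and PT, Sox10 ran from -0.35 to 0.11, Tyr from -0.36 to 0.0786 and Mlana from -0.23 to 0.0777. Kit, also without a call, kept its sign without single arrays in PT against mVec (-0.98 to -0.29) and between T and PT (0.32 to 1.01). Lists with no call also changed the direction of their test, with these medians. In T against mVec, lysosome and autophagy had 0.0330 above the median mean and 0.22 above background, leukocytes 0.0357 after quantile normalization, and above background YAP targets 0.11 and NRF2 targets -0.0995. In PT against mVec, YAP targets had -0.0367 with fry, which passed as higher (adjusted p = 0.00455, range over the alternatives 0.00455 to 0.999) where camera pointed lower without a call, and -0.0399 above the median mean, and glycolysis and hypoxia 0.17 after quantile normalization. Between T and PT, epithelial adhesion had -0.0629 with fry, the same with camera on ranks and -0.0373 after quantile normalization, the interferon list -0.0640 above the median mean, -0.0715 on ranks and -0.0445 after quantile normalization, the invasive state -0.00361 above the median mean and 0.0447 above background, NF-kappaB cytokines 0.0395 after quantile normalization and -0.37 above background, the BCL2 family -0.0855 and YAP targets 0.0133 above background. Without single arrays the list medians in T ran from -0.14 to -0.0627 for keratinocytes, from -0.0405 to 0.0711 for leukocytes and from 0.00399 to 0.23 for lysosome and autophagy. In PT they ran from 0.22 to 0.27 for glycolysis and hypoxia, from 0.0457 to 0.28 for oxidative phosphorylation and from -0.12 to 0.0907 for YAP targets. Between T and PT they ran from -0.0274 to 0.15 for the BCL2 family, -0.0629 to 0.0334 for epithelial adhesion, -0.0614 to 0.20 for heat shock, -0.0845 to 0.00437 for the interferon list, -0.0797 to 0.0732 for NF-kappaB cytokines and -0.13 to 0.31 for oxidative phosphorylation. Signal over background limits the low end: in 2006, 2325 and 560 of the called probe sets of T against mVec, PT against mVec and T against PT both groups were at background.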

Other observations

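The 4 gene groups in this and the next paragraph were chosen after the results were seen, and their camera tests were adjusted over these 4 groups. Genes that assemble ribosomes were higher in both Kit lines. Of 27 measured genes of ribosome biogenesis, 25 rose and 0 fell in T against mVec (median 3.06, adjusted p = 1.95e-18, and 0.0458 with an estimated correlation), and 26 rose and 0 fell in PT (median 3.59, adjusted p = 9.67e-18, and 0.0484 with an estimated correlation). Rrs1, a ribosome assembly factor, was higher by 3.31 ± 0.22 in T, and the snoRNP protein Nop58 by 2.72 ± 0.20, both named after their values were seen. All 27 were above background in T and in PT, and 16 were in mVec. Between T and PT, 7 were lower and 0 higher in T (median -0.20, adjusted p = 0.00027, and 0.302 with an estimated correlation). Of 53 histone genes, 33 rose and 3 fell in T (median 1.10, adjusted p = 8.12e-10, and 0.252 with an estimated correlation) and 45 rose and 3 fell in PT (median 2.06, adjusted p = 6.37e-14, and 0.176 with an estimated correlation), with 15 lower and 0 higher in T than in PT (adjusted p = 5.76e-12, and 0.302 with an estimated correlation). Histone genes have near-identical copies, so that probes can read several of them, and probe sets with the same values on all arrays were counted once.

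Imprinted genes, which are expressed from 1 parental copy, had 9 of 22 lower and 2 higher in T (adjusted p = 0.00232, and 0.187 with an estimated correlation) and 9 lower and 1 higher in PT (adjusted p = 0.00558, and 0.176 with an estimated correlation). Circadian clock genes moved both ways, with 7 of 17 higher and 7 lower in T and 6 higher and 8 lower in PT, and this group did not pass (adjusted p = 0.501 and 0.321). The means in T, PT and mVec were 12.85, 12.93 and 6.42 for the clock repressor Ciart, and 10.14, 9.41 and 7.09 for the clock repressor Cry1, genes named after their values were seen.

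Of the tests below, the quantile normalization of the interferon list and the array pairs of chromosome 10 were written down before their results were seen, and the others after. The first pattern is that Kit and most pigment genes were at background on all 6 arrays, although the cells are labelled as melanocytes and melanoma. Failed arrays or a general misassignment of probe sets are argued against. Of the measured RNA quality genes, 81.25% were above background on all 6 arrays, against 25.6% of all named genes. Bright quality genes do not show whether the probe sets of Kit and the pigment genes read their transcripts, which stays open. Fibroblasts in place of melanocytes stay open in mVec, where 41.7% of the fibroblast list was above background, against 31.7% of all named genes. In T and PT the shares were 16.7% and 0%, against 31.7% and 29.7% of all named genes. On these 12 genes, that argues against fibroblasts in T and PT. Melanocytes that lost the pigment programme stay open in every group. Of the lineage list, 50% was above background in mVec and in T, and 42.9% in PT. In mVec these explanations cannot be told apart, because it held bright markers of both kinds. The lineage genes Pax3 (mean 14.10) and Tfap2a (14.12) were bright there, and so were the fibroblast genes Col1a1 (15.13), Col3a1 (15.81) and Dcn (13.99). Other members were at background in mVec, 7 of 14 lineage genes and 7 of 12 fibroblast genes. Pax3 and Tfap2a were also bright in T (12.20 and 11.84) and in PT (12.78 and 11.65), where 6 and 7 of the 14 lineage genes were at background. The introduced Kit may also not be read by the probe set.

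The second pattern is that most interferon-stimulated genes were above background in mVec (20 of 28) and at background in both Kit lines (25 of 28 in each). Leukocytes in the mVec cultures are argued against, since 0 of the 14 measured leukocyte genes were above background on either mVec array, with 5.60 as their highest log2 value, and scaling by the authors is argued against too, since quantile normalization left the list medians at -4.61 in T and -4.50 in PT. Complete loss of the transcripts of the interferon receptor or of Jak1 is argued against by Ifnar1, Ifnar2 and Jak1, above background in 12 of 12 readings on the T and PT arrays. A partial loss stays open, since all of these were called lower than in mVec (log2 differences in T and PT of -1.73 and -1.73 for Ifnar1, -1.71 and -1.99 for Ifnar2, and -1.46 and -1.31 for Jak1), and the receptor's other kinase, Tyk2, was above background on the mVec arrays alone. A difference between the Kit lines and the vector line that reflects mutant Kit, or the history of each line, was not tested and stays open.

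The third pattern is that genes on chromosome 10 were higher in T than in PT, by a median shift of 0.22 over 329 expressed genes against all 6253, with 64.4% of them above the median difference of all. Against mVec the shift was 0.10 in T and -0.10 in PT. Chance among the 20 chromosomes is argued against by the permutation p of 0.0001, which is the smallest that 10000 permutations of the chromosome labels can give and which treats genes as independent. A single array standing apart is argued against, since the 4 pairs of T and PT arrays gave shifts of 0.17, 0.19, 0.23 and 0.24. An extra copy of the chromosome or a part of it in T, or a loss in PT, stays open as a hypothesis: when its genes were divided in order into 3 parts, the shifts were 0.27, 0.11 and 0.23, where 3 copies against 2 would give 0.58 in every cell, and no DNA was analysed here.

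Many other chromosomes shifted against mVec in both lines. Those with the largest shifts in T were chromosome 3, by 0.50 in T and 0.37 in PT, chromosome 12 by 0.39 and 0.38, chromosome 17 by 0.38 and 0.28, chromosome 9 by -0.36 and -0.46, and chromosome 7 by -0.34 and -0.33. Smaller shifts in T, alike in PT, included chromosome 6 (-0.30 and -0.33) and chromosome 5 (0.23 and 0.25). These shifts were not tested, and the values of the lines are not independent because both use the same mVec arrays.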
